A study of Mus musculus with 8 samples.

How the data were processed

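Total RNA from whole lungs of 8 untreated mice at postnatal day 21 was measured on 8 Affymetrix whole-transcript expression arrays. The labels place 4 mice in a group carrying a stabilized form of beta-catenin and 4 in a group in which beta-catenin was knocked out, number the replicates 1 to 4 within each group as biological replicates, and describe every mouse as male. Beta-catenin, encoded by Ctnnb1, is both the transcriptional effector of canonical Wnt signalling and a component of adherens junctions, and a stabilized form escapes the degradation that normally limits it. The labels give neither the Cre driver nor the altered exons, so the cells that carried each allele are not given in the sources used here. Wild-type or other control lungs were not analysed here, and a difference between the groups therefore does not say which group departed from an unmodified lung.

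Per the labels' protocols, RNA was extracted with spin columns after homogenization and converted to biotin-labelled cRNA. Per the submitters' processing notes, the tools were RMA and the affy package, with no versions given. The deposited values are log2 expression values, 1 per probe set and array, for 34760 probe sets with no missing value. RMA subtracts a modelled background, applies quantile normalization across arrays and summarises the probes of a probe set by median polish, per the usual definition of the method. Quantile normalization gives all arrays nearly the same distribution and would hide a change in total RNA per cell, and background left in dim probe sets compresses their fold changes. The array medians lay between 5.97 and 6.03 on the log2 scale. Arrays carry no read depth, and the precision is limited by the number of arrays, which is 4 per group.

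Gene symbols were taken from the platform annotation supplied with the values. Of the probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had no annotation row, and the latter kinds were left unnamed. Entrez identifiers of 21553 probe sets were found in the RefSeq gene table of the mouse genome, and 0 symbols needed updating. Each gene was represented by its probe set with the highest mean over the 8 arrays, which left 19937 genes, 954 of them with more than 1 probe set. No genome build for the probes is given in the sources used here, so no coordinates are printed, and the gene table was used only for names and for gene order.

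The comparison was fitted with limma (version 3.58.1, in R 4.3.3) using lmFit and eBayes with a constant prior on all 8 arrays, with no covariate and no filter on dim genes. Differences are stabilized minus knockout, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Errors of differences are limma's moderated standard errors (SE), and errors of group means are standard deviations (SD), each with n = 4 per group. The prior contributed 6.20 degrees of freedom, for a total of 12.2.

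Before the data were examined, 40 gene lists holding 880 entries were written for lung cell types, neighbouring tissues, Wnt signalling, metabolism, stress and immune programs. Of these entries, 67 had no match, among them Tcf7, Calca and the haemoglobin genes, which were not analysed here. The rest gave 800 pairs of list and measured gene, in which a gene held by several lists counts once per list. One list of sex-linked genes served as a check of the labels, and the other 39 were tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. For each list the members called over all genes are given, together with the number adjusted over the list alone. Because camera with a preset correlation ignores how strongly the genes of one cell type move together, each list was also tested with a correlation estimated from the data, and with fry (limma), which asks whether the members of a list move without comparing them with other genes. With an estimated correlation 3 of the 39 lists passed, namely ciliated cell markers, airway secretory (club) cell markers and xenobiotic metabolism genes.

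The genes named in the text were fixed by a rule written before the data were examined. It took Ctnnb1, the 12 largest increases and the 12 largest decreases among called genes whose 4 stabilized arrays all lay on one side of all 4 knockout arrays, up to 4 members with the smallest p in each list with a called member, and Scgb1a1, Axin2, Foxj1 and Sftpc whatever their values. Unnamed transcripts such as Riken clones and Gm models were counted but not named. Genes outside this rule are marked in the text as chosen after their values were seen.

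The scripts were tested on simulated data for the stabilized minus knockout comparison over 19937 genes, of which 200 were changed. Of 100 genes changed by 0.5 on the log2 scale 96% were recovered, of 100 changed by 1 on that scale 100% were recovered, and 10 unchanged genes were called. In a simulation of the 39 lists with each gene drawn independently, 3 lists shifted by 0.3 on the log2 scale were called. Before any shift, 0 of the 39 lists were called. Members of the real lists move together, so this simulation does not give the rate of false list calls in these data.

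Alternatives tried were a repeated quantile normalization, centring each array on its median, filters on mean log2 values of at least 4 and 6, a trended and robust prior, array weights, the mean of a gene's probe sets, all probe sets tested separately, the replicate number as a block, other thresholds, and leaving out each array in turn. Xist as a covariate and list tests without genes held by more than 1 list were added after the data were seen. Figures were drawn in Python 3.11.15.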

Results

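The study measured gene expression in lungs of 21-day-old mice with stabilized beta-catenin and with beta-catenin knocked out, and its title names genes that depend on beta-catenin as its subject. Each group held 4 mice, and the only comparison the samples allow is between these groups. Correlations between arrays over all genes ranged from 0.993 to 0.996 within a group and from 0.987 to 0.993 between groups. The first principal component carried 46.2% of the variance and placed all stabilized arrays on one side and all knockout arrays on the other, and the next carried 14.1%. The closest pair of arrays differed by a root mean square of 0.251 on the log2 scale, so no array was a copy of another.

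**Figure D1:**
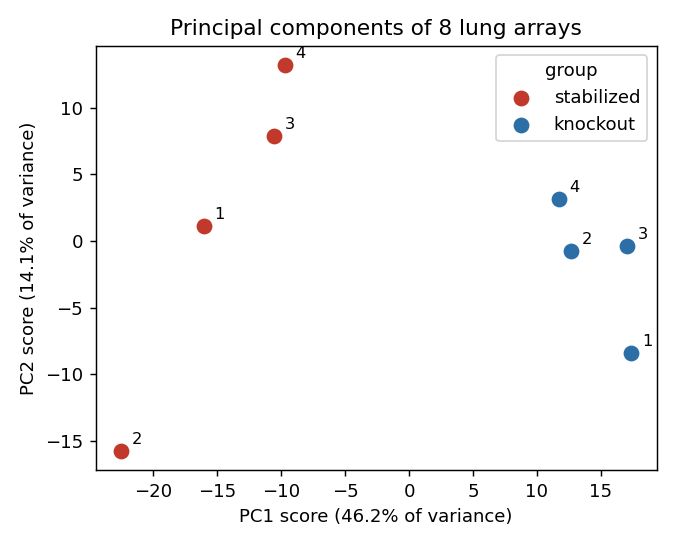
Principal component scores of the 8 arrays over all genes, with the first component on the x axis (46.2% of variance) and the next on the y axis (14.1% of variance), coloured by group and numbered by replicate. All 4 stabilized arrays have negative scores on the first component and all 4 knockout arrays positive ones, and stabilized replicate 2 lies furthest from its group at -22.50 and -15.74.

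Ctnnb1 transcript itself did not differ between the groups. Its log2 expression was 11.14, 11.12, 11.02 and 10.99 in stabilized replicates 1 to 4 and 10.98, 10.99, 10.92 and 11.03 in knockout replicates 1 to 4, a difference of 0.09 ± 0.06 (SE, n = 4 per group, limma adjusted p = 0.42). The gene has 1 probe set on the array. The labels do not say which exons were altered or in which cells, so this value does not check the genotype labels. The list of 20 genes of the beta-catenin complex and adherens junctions had 0 called members (camera adjusted p = 0.39), 0 when adjusted over the list alone, and a median difference of 0.02.

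The sex recorded for the mice was not borne out by the sex-linked genes in 4 of the 8 arrays. Xist, which is transcribed from the inactive X chromosome of females, was at a log2 value of 10.59 and 10.36 in stabilized replicates 1 and 4 and 10.55 and 10.42 in knockout replicates 1 and 3, against 4.18 to 4.62 in the other arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty lay between 3.08 and 4.00 in these same 4 arrays and between 6.71 and 8.35 in the others. Each group thus held 2 arrays of either pattern, and none of the 4 sex-linked genes differed between the groups (limma adjusted p of at least 0.91). The sources used here do not settle whether the recorded sex is wrong or samples were exchanged. Arrays of both patterns lay on their own group's side of the first principal component, and no array lay among those of the other group. With Xist as a covariate, an alternative added after the data were seen, 1775 genes were called, 1711 of them among those called without it.

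Between the groups, 1917 of 19937 genes (9.62%) were called, 928 higher and 989 lower in stabilized lungs (limma, Benjamini-Hochberg adjusted p under 0.05). The median difference was 0.35 among called genes that were higher and -0.44 among those that were lower, and of the changes of at least 1 on the log2 scale 20 were higher and 74 lower. The groups did not overlap in 3367 genes (16.9%), where chance gives 2.86%. The split into higher and lower genes depended on scaling: after centring each array on its median, 1495 of 2321 called genes (64.4%) were higher, against 48.4% without centring. Leaving out stabilized replicate 1 reduced the called genes to 1216, and leaving out knockout replicate 3 reduced them to 1235.

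Airway epithelial genes were lower in stabilized lungs. Of 21 markers of airway secretory (club) cells, the cells that make secretoglobins and detoxifying enzymes in the bronchioles, 0 rose, 17 fell and 4 did not pass the test (19 fell when adjusted over the list alone). Scgb3a2, a secretoglobin of the conducting airway, was 3.24-fold lower at a log2 value of 7.31 ± 0.05 in stabilized and 9.01 ± 0.21 in knockout lungs (SD, n = 4). Reg3g, an antimicrobial lectin, showed the largest decrease of any named gene at 10.5-fold (log2 difference -3.40 ± 0.34, SE, limma adjusted p = 5.7e-05), and Bpifa1, a secreted airway defence protein, fell by 2.23 ± 0.37 (SE). Cyp2f2, a cytochrome P450 of club cells, fell by 0.92 ± 0.08 (SE). Scgb1a1, the most abundant club cell secretory protein, fell by 0.51 ± 0.08 (SE, limma adjusted p = 0.0014). Scgb1a1 lay at 12.38 in stabilized and 12.89 in knockout lungs, not far below the array maxima of 13.4 to 13.7, so its change may be compressed. Scgb3a1 and Chad also fell, by 1.88 ± 0.27 and 1.66 ± 0.13 (SE). The list had a median difference of -0.68 (camera adjusted p = 3.6e-18, and adjusted p = 0.024 with an estimated correlation).

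Ciliated cell genes moved the same way. Of 34 markers of ciliated cells, 0 rose, 26 fell and 8 did not pass the test (32 fell when adjusted over the list alone), with a median difference of -0.66 (camera adjusted p = 1.6e-30, and adjusted p = 0.024 with an estimated correlation). Dnah5 and Dnah9, heavy chains of the dynein arms that drive ciliary beating, were 2.55-fold and 1.93-fold lower, with log2 differences of -1.35 ± 0.08 and -0.95 ± 0.07 (SE, n = 4 per group). Hydin, a component of the ciliary central pair, fell by 0.97 ± 0.07, the cadherin Cdhr3 fell by 1.22 ± 0.10, and Foxj1, the transcription factor of motile ciliogenesis, fell by 0.62 ± 0.08 (SE). With each array left out in turn, 24 to 28 ciliated and 16 to 17 club markers were lower.

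Mucous (goblet) cell markers went both ways. Of 15 measured, 4 fell, 1 rose and 10 did not pass the test (6 and 3 when adjusted over the list alone). The mucins Muc5b and Muc5ac fell by 1.83 ± 0.20 and 0.65 ± 0.14, the trefoil peptide Tff2 fell by 1.35 ± 0.13, and lactoferrin (Ltf) fell by 0.89 ± 0.15 (SE, n = 4 per group). The member that rose was the anion exchanger Slc26a4, chosen after its values were seen, at 1.09 ± 0.27 (SE, limma adjusted p = 0.027). No member rose without stabilized replicate 1 or 3 or without knockout replicate 2 or 4, while 3 rose without stabilized replicate 2 and 2 without knockout replicate 1. The list's camera adjusted p was 0.0076, and its adjusted p = 0.44 with an estimated correlation.

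Xenobiotic metabolism genes, many of which club cells express, were lower in stabilized lungs. Of 32 measured, 13 fell, 1 rose and 18 did not pass the test (16 and 3 when adjusted over the list alone), with a median of -0.27 (camera adjusted p = 5.6e-08, and adjusted p = 0.039 with an estimated correlation). The cytochrome P450 Cyp2s1 fell by 1.19 ± 0.09, the glutathione transferase Gsta4 fell by 0.92 ± 0.10 and the alcohol dehydrogenase Adh7 fell by 0.74 ± 0.07 (SE). Cyp1b1, chosen after its values were seen, rose by 0.62 ± 0.07 (SE, limma adjusted p = 2.6e-04).

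Other airway lists showed no group-wide difference. Of 11 basal cell markers, the transcription factor Snai2 rose by 0.37 ± 0.08 (SE), Aqp3 fell by 0.39 ± 0.10 (SE) and 9 did not pass the test (1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.57). The call of Aqp3 was lost in 4 of the 8 fits that left out 1 array (highest adjusted p = 0.097). Of 14 neuroendocrine cell markers 0 passed (0 when adjusted over the list alone; camera adjusted p = 0.53), with a median of -0.03. Of 25 lung epithelial transcription factors, Hey1 (0.56 ± 0.11, SE), Irx1 and Irx3 rose and 22 did not pass (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.29). The calls of Irx1 and Irx3 were lost after repeated quantile normalization (adjusted p = 0.065 and 0.070) and in 5 and 6 of the 8 fits that left out 1 array. Of 19 intestinal lineage genes only Lyz1, which type 2 cells of mouse lung also express, rose (0.37 ± 0.09, SE), and 18 did not pass (1 rose when adjusted over the list alone; camera adjusted p = 0.16). The call of Lyz1 was lost in 7 of the 8 fits that left out 1 array (highest adjusted p = 0.089).

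**Figure D2:**
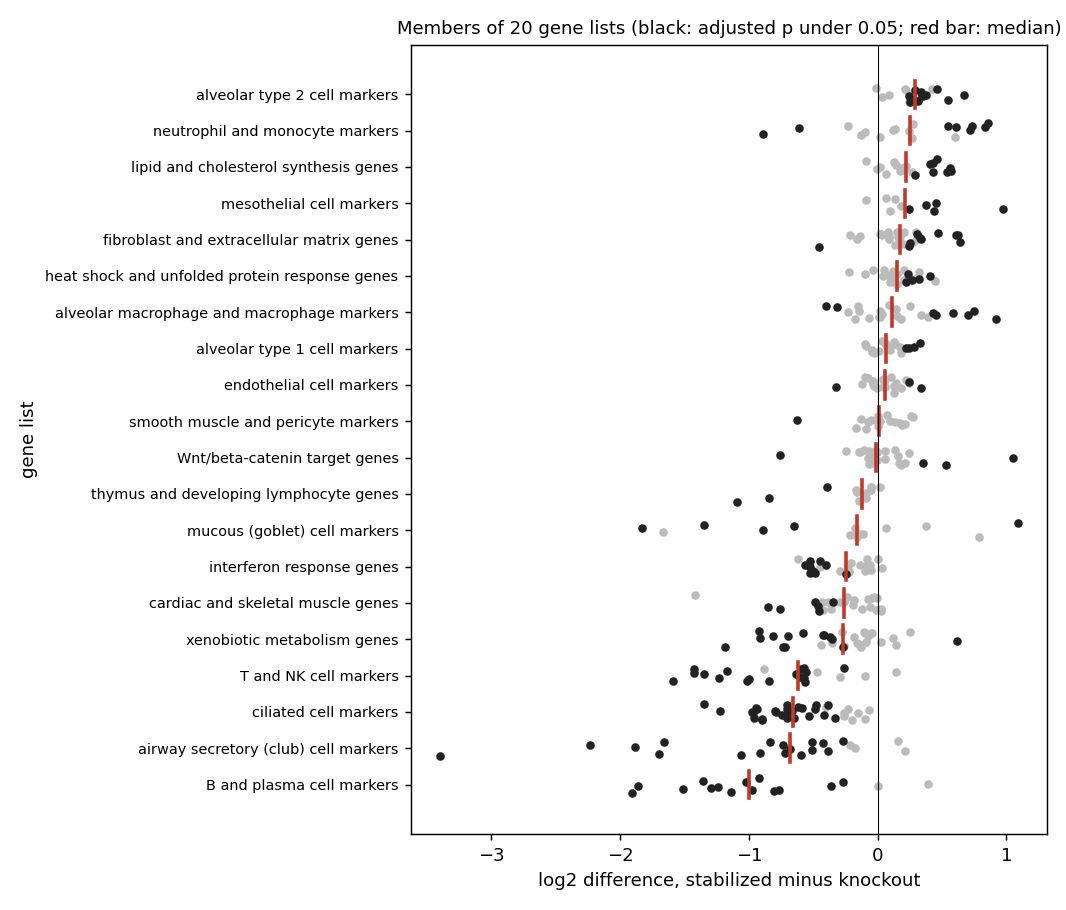
Differences of single genes (log2, stabilized minus knockout, x axis) in 20 gene lists (y axis), with genes past the limma threshold in black, others in grey and the list median as a red bar. The markers of club cells, ciliated cells and B cells lie almost wholly below 0 with medians of -0.68, -0.66 and -0.999, and those of alveolar type 2 cells lie mostly above 0 with a median of 0.29.

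Alveolar type 2 cell genes were modestly higher in stabilized lungs. Of 22 markers of these surfactant-producing cells, 13 rose, 0 fell and 9 did not pass the test (18 rose when adjusted over the list alone), with a median of 0.29. Lamp3, a protein of lamellar bodies, was 1.46-fold higher at 10.67 ± 0.11 against 10.12 ± 0.09 (SD, n = 4), and Egfl6 rose by 0.67 ± 0.09 (SE). The surfactant protein gene Sftpd and the phospholipid transporter gene Abca3 rose by 0.46 ± 0.07 and 0.34 ± 0.07 (SE), whereas Sftpc, the type 2 surfactant protein gene, differed by 0.03 ± 0.08 (SE, limma adjusted p = 0.83). Sftpc lay at 13.2 in both groups, close to the array maxima of 13.4 to 13.7, where a probe set responds less to a change. The camera adjusted p was 6.9e-11, with adjusted p = 0.15 with an estimated correlation. Without stabilized replicate 1 only 4 of these markers passed, and with any other single array left out 6 to 12 passed.

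Cholesterol and lipid synthesis genes rose alongside them. Of 19 measured, 8 rose, 0 fell and 11 did not pass (12 rose when adjusted over the list alone), with a median of 0.22 (camera adjusted p = 1.2e-08, and adjusted p = 0.055 with an estimated correlation). Lss, Cyp51 and Idi1, which encode enzymes of sterol synthesis, rose by 0.54 ± 0.07, 0.57 ± 0.08 and 0.57 ± 0.08, and squalene epoxidase (Sqle) rose by 0.43 ± 0.06 (SE, n = 4 per group). With each array left out in turn, 7 to 8 members rose.

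Of 20 markers of alveolar type 1 cells, the flat cells of gas exchange, 4 rose, 0 fell and 16 did not pass (5 rose when adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation). Spock2 rose by 0.33 ± 0.06 and Krt7 by 0.28 ± 0.06 (SE), and the other members past the threshold were Agrn and Limch1, lost in 7 and 8 of the 8 fits that left out 1 array (highest adjusted p = 0.13 for each). Without stabilized replicate 1 only 1 member passed, and the list's call was lost without stabilized replicate 3 (adjusted p = 0.057) or knockout replicate 1 (adjusted p = 0.064).

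Lymphocyte genes were lower in stabilized lungs. Of 16 markers of B and plasma cells, 0 rose, 14 fell and 2 did not pass the test (14 fell when adjusted over the list alone). Cd79a, a chain of the B cell receptor complex, was 3.62-fold lower at 5.40 ± 0.22 against 7.26 ± 0.20 (SD, n = 4). Ms4a1, which encodes CD20, fell by 1.91 ± 0.16, Cd79b fell by 1.35 ± 0.09 and the complement receptor Cr2 fell by 0.97 ± 0.07 (SE). The list's median was -0.999 (camera adjusted p = 1.9e-17, and adjusted p = 0.053 with an estimated correlation). Of 22 markers of T and NK cells, 0 rose, 17 fell and 5 did not pass (20 fell when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 8.7e-16, and adjusted p = 0.15 with an estimated correlation). Cd8a was 3.01-fold lower at 6.24 ± 0.29 against 7.82 ± 0.43 (SD, n = 4). Cd8b1 and the interleukin-7 receptor gene Il7r each fell by 1.43, with SE of 0.19 and 0.11, and the NK receptor gene Klrd1 fell by 1.23 ± 0.14 (SE). With each array left out in turn, 12 to 14 B cell and 14 to 17 T and NK cell markers were lower. Genes of cardiac and skeletal muscle were lower alongside these markers, with 6 of 25 lower (median -0.26, camera adjusted p = 3.5e-06, and adjusted p = 0.18 with an estimated correlation). In knockout replicates 1 to 4 the mean log2 level was 6.95, 6.71, 7.04 and 6.71 for the muscle list and 6.90, 6.43, 6.69 and 6.28 for the T and NK cell list. In stabilized replicates 1 to 4 the muscle list lay at 6.52, 6.56, 6.47 and 6.60 and the T and NK cell list at 5.66, 5.74, 5.95 and 5.87. Stabilized replicate 3 was thus lowest for muscle and highest for T and NK cells, so the lists did not move together in that group. Among knockout lungs, however, replicates 1 and 3 were highest for both lists, and whether the lists share a source there was not tested. Of 14 adipose genes 1 was lower (median -0.16, camera adjusted p = 0.0058, and adjusted p = 0.33 with an estimated correlation).

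Genes of related immune programs were lower as well. Ccl5, a chemokine made by T and NK cells, fell by 1.95 ± 0.16, and Ms4a4b and the lymphoid transcription factor Ikzf3 fell by 1.93 ± 0.18 and 1.69 ± 0.14 (SE, n = 4 per group). Ms4a4b belongs to a family of similar genes, which probes may not fully tell apart. Of 12 thymus and developing lymphocyte genes, Satb1, Themis and Ccr9 fell, the first by 0.84 ± 0.12 and the next by 1.09 ± 0.20 (SE), and 9 did not pass (3 fell when adjusted over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.17 with an estimated correlation). Ccr9 lost its call in 6 of the 8 fits that left out 1 array (highest adjusted p = 0.094). Of 22 mast cell, eosinophil and dendritic cell markers, 6 fell and 16 did not pass (8 fell and 1 rose when adjusted over the list alone). Among these, the chemokine receptor Ccr7 fell by 1.00 ± 0.11 and Clec9a, a receptor of cross-presenting dendritic cells, fell by 0.84 ± 0.15 (SE; camera adjusted p = 0.0087, and adjusted p = 0.17 with an estimated correlation).

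Of 10 lymphoid tissue chemokines and partners, Ltb, Cxcr5 and Clu fell by 0.66 ± 0.09, 0.67 ± 0.11 and 0.34 ± 0.07, while the B cell attractant Cxcl13 rose by 0.66 ± 0.12 (SE; 1 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.053). Of 25 interferon response genes, 10 fell, 0 rose and 15 did not pass (13 fell when adjusted over the list alone), with a median of -0.24. Ifit3, Zbp1 and Bst2 fell by 0.53 ± 0.09, 0.56 ± 0.12 and 0.49 ± 0.10 (SE; camera adjusted p = 6.8e-07, and adjusted p = 0.33 with an estimated correlation). With each array left out in turn 3 to 12 passed, and 3 was the count without stabilized replicate 2, knockout replicate 2 or knockout replicate 4. Of 16 antigen presentation genes, Psmb9, Nlrc5 and Tap1 fell by 0.32 ± 0.08, 0.29 ± 0.08 and 0.35 ± 0.10 (SE) and 13 did not pass (5 fell when adjusted over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.44 with an estimated correlation). The 19 probe sets of Nlrc5 differed by -0.17 to -1.06, and the brightest, used here, gave -0.29. None of the 3 passed without stabilized replicate 1 or 2 or without knockout replicate 2 or 3, while 5 members fell without stabilized replicate 3 and 4 without knockout replicate 4.

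Beside these lymphocyte genes, markers of blood cells went different ways. Of 9 platelet genes, Tubb1 fell by 0.42 ± 0.12 (SE), a call lost in 5 of the 8 fits that left out 1 array, and 8 did not pass (1 fell when adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.031, and adjusted p = 0.49 with an estimated correlation). The platelet list lost its call in 4 of those fits (highest adjusted p = 0.12). Of 5 erythroid genes, Bpgm and Alas2 rose by 0.71 ± 0.11 and 0.64 ± 0.11 (SE) and 3 did not pass (3 rose when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.0087, and adjusted p = 0.33 with an estimated correlation). Of 18 neutrophil and monocyte markers, 6 rose, 2 fell and 10 did not pass (9 and 2 when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0017, and adjusted p = 0.17 with an estimated correlation). The neutrophil collagenase Mmp8 rose by 0.83 ± 0.08, the chemokine receptor Cxcr2 by 0.86 ± 0.13, the growth factor receptor Csf3r by 0.73 ± 0.11 and S100a9 by 0.72 ± 0.09 (SE). The members that fell were Ltf and Plac8, the latter chosen after its values were seen, at -0.61, and 1 member fell without stabilized replicate 1, 2 or 4 or without knockout replicate 1 or 3.

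Of 24 macrophage markers, 6 rose, 2 fell and 16 did not pass (7 and 2 when adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0089, and adjusted p = 0.29 with an estimated correlation). The macrophage elastase Mmp12 rose by 0.92 ± 0.16, the scavenger receptor Msr1 by 0.70 ± 0.11, and the complement genes C1qa and C1qb by 0.59 ± 0.08 and 0.45 ± 0.08 (SE). The members that fell were Cd163 and Plet1, chosen after their values were seen, at -0.40 and -0.32, and 0 members fell without stabilized replicate 1 or 4 or without knockout replicate 1 or 2. The list's call was lost without knockout replicate 4 (adjusted p = 0.055). Of 37 inflammatory cytokines and chemokines, 6 rose, 1 fell (Ccl5) and 30 did not pass (7 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.10). Il1b and the alarmin Il33 were 2.23-fold higher each, with log2 differences of 1.16 ± 0.10 and 1.16 ± 0.09, and Ccl9 rose by 0.55 ± 0.10 (SE).

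Canonical Wnt target genes did not differ as a group in whole lung. The cells that carried each allele are not given, so these values do not show whether targets changed within those cells. Of 28 measured, 3 rose, 1 fell and 24 did not pass (3 and 1 when adjusted over the list alone). Axin2, a feedback inhibitor widely used as a Wnt readout, was at 7.26 ± 0.07 in stabilized and 7.20 ± 0.12 in knockout lungs (SD, n = 4), a difference of 0.06 ± 0.07 (SE, limma adjusted p = 0.67). Wif1, a secreted Wnt inhibitor, rose by 1.05 ± 0.21, Bmp4 by 0.53 ± 0.11 and the receptor gene Tnfrsf19 by 0.35 ± 0.08, while Lef1, a transcriptional partner of beta-catenin that lymphocytes also express, fell by 0.76 ± 0.10 (SE). The list's median was -0.02, and its mean of 0.05 and the camera test pointed to higher values (camera adjusted p = 0.54). Tnfrsf19 lost its call without stabilized replicate 1 (adjusted p = 0.061) or knockout replicate 3. Of 32 Wnt ligands, receptors and inhibitors, Wnt2 rose by 0.64 ± 0.09, Ryk rose by 0.24 ± 0.06 and Porcn fell by 0.36 ± 0.08 (SE), and 29 did not pass (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.79). Ryk lost its call in 7 of the 8 fits that left out 1 array (highest adjusted p = 0.099), and Wnt4 differed by -0.20 ± 0.06 (SE, adjusted p = 0.071).

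**Figure D3:**
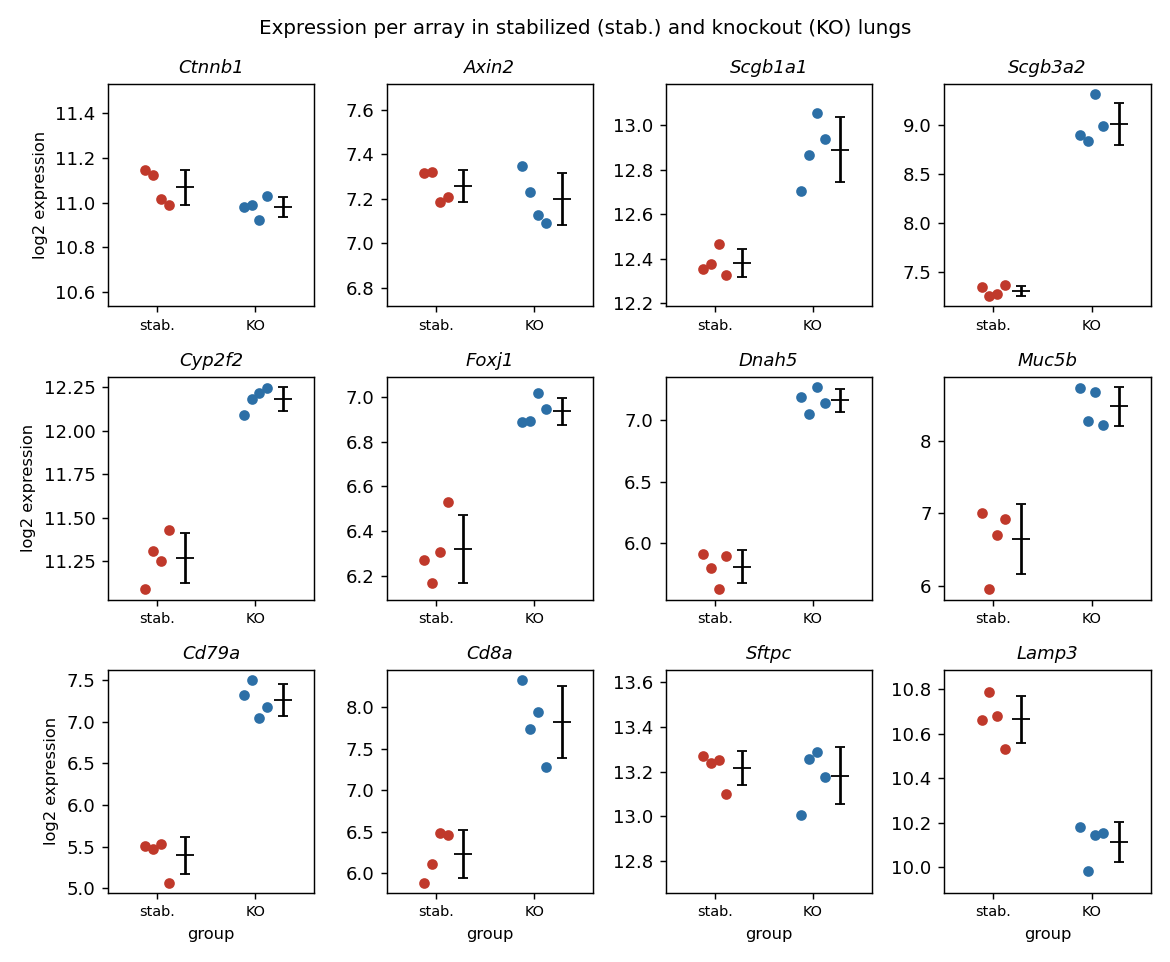
Log2 expression of 12 named genes (y axis) in each of 4 stabilized (red) and 4 knockout (blue) lungs, with the group mean and SD as black bars beside the points. Ctnnb1, Axin2 and Sftpc overlap between the groups, Lamp3 lies higher in all stabilized arrays and the other 8 genes lie lower in all of them.

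Fibroblast and extracellular matrix genes were higher in stabilized lungs. Of 29 measured, 9 rose, 1 fell and 19 did not pass (11 and 2 when adjusted over the list alone), with a median of 0.17 (camera adjusted p = 1.7e-05, and adjusted p = 0.20 with an estimated correlation). Fibronectin (Fn1) rose by 0.61 ± 0.08, the lung mesenchyme transcription factor Tcf21 by 0.64 ± 0.11 and lysyl oxidase (Lox) by 0.47 ± 0.08, while Fbln1 fell by 0.45 ± 0.07 (SE). Of 18 smooth muscle and pericyte markers, Hhip fell by 0.63 ± 0.12 (SE) and 17 did not pass (1 fell when adjusted over the list alone; median 0.01, camera adjusted p = 0.54). Rgs5, a G-protein regulator characteristic of pericytes that the rule named by size, was 3.14-fold higher. Of 24 endothelial markers, Flt4 and Esam rose by 0.33 ± 0.07 and 0.24 ± 0.07, Lyve1 fell by 0.32 ± 0.09 (SE) and 21 did not pass (4 and 1 when adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.28 with an estimated correlation). The calls of Esam and Lyve1 were lost in 7 and 6 of the 8 fits that left out 1 array (highest adjusted p = 0.11 and 0.10), and that of the list without knockout replicate 1 (adjusted p = 0.077) or knockout replicate 2 (adjusted p = 0.061).

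The largest increases named by the rule were led by Ang5. This gene, of the angiogenin family of ribonucleases, was 4.66-fold higher at 7.44 ± 0.21 against 5.22 ± 0.32 (SD, n = 4, limma adjusted p = 2.7e-06), although its near-identical relatives may share its probes. The chloride channel gene Cftr was 3.99-fold higher and the protease inhibitor gene Spink5 3.81-fold higher, with log2 differences of 2.00 ± 0.14 and 1.93 ± 0.14 (SE). Lrg1, Mfsd2a, a transporter of lysophosphatidylcholine, and Ctse, an aspartic protease, rose by 1.61 ± 0.15, 1.53 ± 0.11 and 1.25 ± 0.11 (SE). The glutamate receptor subunit gene Grin2c, the bradykinin receptor gene Bdkrb2 and the amino acid transporter gene Slc1a4 rose by 1.17 ± 0.09, 1.12 ± 0.13 and 1.11 ± 0.11 (SE). On the other side, Ublcp1, a phosphatase gene of no list, was 5.85-fold lower at 5.34 ± 0.17 against 7.89 ± 0.33 (SD, n = 4, limma adjusted p = 1.3e-06).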

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

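The test for a single outlying array was fixed before the data were examined. Within each group of 4 arrays, the gap between the most extreme array and its nearest neighbour was divided by the range of the group, for every named gene and list mean. Of 412 groups, 24 exceeded Dixon's critical value for groups of 4, where chance alone gives about 20.6, so the number of such values was close to that of chance.

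Among knockout lungs, replicate 1 stood apart in 8 cases. It was low for the protease gene Ctse (ratio 0.902, log2 value 5.65 against 5.98 to 6.01 in the others), the mesothelial gene Msln (0.933), the neutrophil receptor gene Csf3r (0.921) and the chaperone gene Hspd1 (0.841). Its mean was low for the platelet list (0.941, 6.49 against 6.75 to 6.77) and the fibroblast list (0.843), and high for the cell cycle list (0.846, 6.54 against 6.31 to 6.35) and the Wnt target list (0.888, 6.72 against 6.65 to 6.66). Knockout replicate 3 was high for C1qa (0.830) and knockout replicate 4 was low for Tap1 (0.853).

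Among stabilized lungs, replicate 4 was low for the B cell gene Cd79a (0.865, 5.07 against 5.48 to 5.54), for Hhip (0.860) and for the cell cycle gene Prc1 (0.840), and high for Adh7 (0.879), Lgr6 (0.918) and S100b (0.832). Replicate 2 was low for Chad (0.836), for the platelet genes Tubb1 (0.853) and Ppbp (0.918, 7.70 against 8.48 to 8.55) and for the mean of the mucous cell list (0.985, 5.36 against 5.82 to 5.83), the highest ratio of all. Replicate 3 was high for C1qa (0.912) and Tap1 (0.882). Replicate 1 was high for Tcf21 (0.834) and low for Klrd1 (0.879).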

How the results depend on the processing

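The Xist covariate and the list tests without shared genes were chosen only after the result was seen. At an adjusted p under 0.01 limma called 891 genes (358 higher, 533 lower), under 0.10 it called 2998 (1507 higher, 1491 lower), and with a change of at least 1 on the log2 scale 94 (20 higher, 74 lower), all following from the threshold. Median centring gave 1495 higher genes, with a median shift of all genes of 0.03. Leaving out each array in turn gave 1216 to 1839 genes, of which 503 to 882 were higher, with fewer samples in each fit. The remaining settings, centring included, called 1535 to 2321 genes, the lowest being all 34760 probe sets tested separately. With the replicate number as a block, 1828 genes were called, 1646 of them shared with the unblocked fit. Deviations of same-numbered arrays correlated at 0.08, 0.07, -0.01 and 0.02, and 2 of 8 arrays correlated best with their own number. These values showed no clear pairing by number, but 4 arrays per group are too few to exclude one. The Ctnnb1 difference passed in no setting and lay between 0.06 and 0.12 with single arrays left out. Of the 39 lists, camera called 26, camera with an estimated correlation called 3 and fry called 16. With an estimated correlation the adjusted p was 0.0526 for B cells, 0.151 for T and NK cells, 0.151 for type 2 cells and 0.0550 for lipid synthesis, because the members of each list move together between arrays. Fry's test of change in either direction, which asks whether any members change, gave an adjusted p of 1.28e-06 for Wnt targets. That test called 37 of the 39 lists, so it does not set Wnt targets apart. Among them were the beta-catenin complex and neuroendocrine lists, each with 0 called members (fry adjusted p = 0.0226 and 0.0148). Ciliated, club, B cell, T and NK cell, type 2 and lipid lists kept their direction and call in all other settings. Among the other lists, 4 lost their call after repeated quantile normalization. With a filter on mean log2 values of at least 6, 5 lost it, and with one of at least 4, 1 lost it. Without shared genes the cartilage list was lost (adjusted p = 0.24). Besides Ctnnb1, 133 of 166 named genes were called. Over 2792 pairs of gene and setting 2542 calls were the same, 195 were lost, 55 were gained and 0 reversed direction, and 32 genes lost their call somewhere, the cause of which was not tested. The planned removal of probe sets with _x_at, _s_at or _a_at endings and the Gapdh covariate for RNA quality were not run, since the annotation used here marks no such probe sets. Dim genes limit the range: with a mean log2 value of at least 6, 1841 of 11400 genes were called, 61.9% of them higher.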

Other observations

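The tests of the club cell, lymphocyte and Ctnnb1 neighbour patterns were chosen only after the result was seen, while the splits of the arrays and the ciliated cell test were set before. Genes of tissues at the border of the lung differed between the groups. Of 25 cardiac and skeletal muscle genes, 0 rose, 6 fell and 19 did not pass the test (13 fell when adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.5e-06, and adjusted p = 0.18 with an estimated correlation). Phospholamban (Pln) fell by 0.85 ± 0.15, myoglobin (Mb) by 0.76 ± 0.11 and Actn2 by 0.45 ± 0.10 (SE, n = 4 per group, limma), genes that heart muscle and the pulmonary vein share. Of 10 markers of mesothelium, the outer covering of the lung, 5 rose and 5 did not pass (5 rose when adjusted over the list alone), with a median of 0.21 (camera adjusted p = 5.4e-05, and adjusted p = 0.053 with an estimated correlation). Upk1b was 1.97-fold higher at 9.49 ± 0.14 against 8.51 ± 0.03 (SD, n = 4), and Msln rose by 0.45 ± 0.07 (SE). Without knockout replicate 3 only 2 of these members passed, and without knockout replicate 4 only 3.

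Of 23 heat shock and unfolded protein response genes, 5 rose and 18 did not pass (6 rose when adjusted over the list alone; camera adjusted p = 9.4e-05, and adjusted p = 0.25 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 rose by 0.41 ± 0.07 and the disulfide isomerase Pdia6 by 0.32 ± 0.07 (SE), and without stabilized replicate 1 or knockout replicate 3 only 1 member passed. Of 16 circadian clock genes, Hlf, Nr1d1 and Cry2 fell by 0.54 ± 0.10, 0.43 ± 0.09 and 0.27 ± 0.07 and Clock rose by 0.35 ± 0.09 (SE; 1 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.020, and adjusted p = 0.35 with an estimated correlation). Cry2 and Clock lost their calls in 6 and 4 of the 8 fits that left out 1 array. Without stabilized replicate 3, 6 clock genes fell and 2 rose, and the list lost its call without knockout replicate 3 (adjusted p = 0.074). Of 20 glucocorticoid and hypoxia response genes, the metallothioneins Mt2 and Mt1 fell by 1.04 ± 0.23 and 0.66 ± 0.18 and Hk2 rose by 0.24 ± 0.07 (SE; 2 and 2 when adjusted over the list alone; camera adjusted p = 0.36). Both metallothioneins lost their calls with a trended and robust prior (adjusted p = 0.074 and 0.095). Mt2 also lost its call without stabilized replicate 2 (adjusted p = 0.052), Mt1 in 6 of the 8 fits that left out 1 array, and Hk2 lost its call whichever array was left out. Of 37 cell cycle genes, Prc1 and Bub1 rose by 0.53 ± 0.10 and 0.60 ± 0.17 (SE; 1 rose when adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.49 with an estimated correlation). Bub1 lost its call in 6 of the 8 fits and the list in 3 of the 8.

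The remaining lists each held at most 1 called gene in a direction. Of 24 immediate early genes, Ier3 rose by 0.35 ± 0.08 and Nr4a2 fell by 0.31 ± 0.09 (SE; 1 and 1 when adjusted over the list alone; camera adjusted p = 0.20), and Nr4a2 lost its call in 6 and Ier3 in 2 of the 8 fits that left out 1 array, while 3 members fell without stabilized replicate 4 and 2 without knockout replicate 4. Of 12 nerve and glia genes, Mal rose by 0.34 ± 0.07 and Cnp fell by 0.26 ± 0.07 (SE; 1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.24), and Cnp lost its call in 7 of those fits. Of 14 adipose genes, Cidec fell by 0.42 ± 0.09 (SE; 3 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.0058, and adjusted p = 0.33 with an estimated correlation), and 3 fell without stabilized replicate 4 or knockout replicate 2 and 2 without knockout replicate 1. Of 16 cartilage genes only Chad fell, which the club cell list also holds (1 when adjusted over the list alone; camera adjusted p = 0.042, and adjusted p = 0.49 with an estimated correlation). The cartilage list lost its call in 4 of the 8 fits that left out 1 array (highest adjusted p = 0.11). Of 13120 probe sets with no gene symbol or several, 323 were called when all probe sets were tested.

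Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real one, called as many genes (1917 against at most 4 in any other split). The split with 4 called genes set the arrays with high Xist against the others, and the remaining splits called 0. Chance is therefore an unlikely source of the gene count, although a rank of 1 among 35 is the strongest result this test can give. The real split also called the most lists (26), but another split called 22 lists with 0 genes called. The list count therefore sets the real split apart only narrowly, and chance was not excluded for it. Single lists were compared over the splits only if they had the smallest camera p in the real one, which favours the real split in advance. Their ranks are therefore no independent evidence. By camera, the smallest p over all splits came from the real one for the lists of ciliated cells (4.2e-32 against 3.5e-17 in the next split), club cells (1.9e-19 against 2.2e-11), B cells (1.5e-18 against 8.7e-11), T and NK cells (8.9e-17 against 2.7e-14) and lipid synthesis (1.8e-09 against 3.3e-07). For the type 2 cell list 2 of the 35 splits gave as small a p (8.9e-12 against 7.4e-12), so chance was not excluded there. The other of these splits exchanged stabilized replicate 4 with knockout replicate 3 and called 0 genes.

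A candidate explanation for the lower airway genes is a smaller share of airway tissue in the stabilized samples, which would lower all airway markers by about the same factor. Of 15 club cell markers bright enough to compare, 3 fell by more than Cyp2f2 within the same arrays at an adjusted p under 0.05 for the difference (limma). These were Scgb3a1, Scgb3a2 and Chad (by -0.96, -0.78 and -0.74 relative to Cyp2f2), but all 3 were named for the size of their decrease. At the same threshold 8 others changed by less, and Cyp2f2 at 11.3 to 12.2 is bright enough for its change to be compressed. Of 34 ciliated cell markers only 2, Dnah5 and Cdhr3, fell by more than Cyp2f2 at that threshold (by -0.43 and -0.31), while many others changed by less. The fit gave all 34 of these differences the same SE of 0.108, so no gene's own variance entered, and all share the Cyp2f2 values. Changes of unequal size go against 1 common factor, but compression in dim or bright probe sets would also make them unequal. In both cell types a smaller airway share therefore cannot be told apart from a change in the cells themselves. A change in airway cell differentiation that depends on beta-catenin stays open and was not tested against a control lung.

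The lower B and T cell markers may reflect lymphocytes in the lung itself or another tissue taken along with the knockout samples. More blood in the knockout samples, which would raise all blood markers there, is argued against as the whole cause by the erythroid genes, with a median of 0.54 and Bpgm and Alas2 higher in stabilized lungs, although the platelet median of -0.15 lay the other way and the erythroid list had adjusted p = 0.33 with an estimated correlation. Thymus tissue cannot be told apart, since the median of Rag1, Rag2, Dntt, Ptcra and Arpp21 was -0.0909 but all 5 lay below the median of all probe sets in both groups. Lymph node tissue stays open too, since Cxcl13, Ccl19, Glycam1 and Madcam1 had a median of 0.0702 but Glycam1 and Madcam1 lay below that median in both groups, Cxcl13 in knockout lungs, and Cxcl13 and Ccl19 went opposite ways (0.66 and -0.31), while Ltb, Cxcr5 and Ccr7 fell. A difference in lymphocyte number or lymphoid aggregates of the lung also stays open, as does other adjoining tissue, since muscle genes (median -0.26) and adipose genes (median -0.16) were lower alongside, and neither was tested.

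Large changes could also come from alleles carried along with the modified Ctnnb1 locus. Of 92 genes with a known position and a change of at least 1 on the log2 scale, 0 lay among the 50 nearest neighbours of Ctnnb1, 25 on each side in the order of the mouse gene table. None of these changes was therefore in a gene of that short stretch, where few would lie in any case. A longer linked stretch was not examined, and alleles shared by both groups would not show, so linked alleles beyond it stay open. Of the neighbours 4 (8%) were called, against 9.61% of all genes (Fisher's exact test, two-sided, p = 1). Strain differences elsewhere in the genome were not tested, and Ublcp1, with a 5.85-fold difference, belongs to no list. The sources used here give no array run dates, so a batch that coincided with genotype was not tested.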
